A study of Homo sapiens with 2 samples.

How the data were processed

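The series holds 2 single-colour arrays of total RNA from SK-NEP-1 cells, 1 from DMSO and 1 from 2 µM SKI-5C. Groups were taken from the treatment given in the labels. The growth protocol in the labels also mentions another compound, LBH589, and the wording of the 24-hour time is ambiguous, so both are taken here as the treatment labels give them. Per the labels' protocols, ribosomal RNA was removed before amplification, and the cRNA was labelled with Cy3 and hybridised to an Arraystar human array of long noncoding and coding transcripts.

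The scanner files hold spot intensity. Per the file headers, these intensity values were extracted with Agilent Feature Extraction 11.0.1.1 from an array design on genome build hg19; the submitters' processing notes name version 10.7.3.1. The processed intensity is background-subtracted and spatially detrended, per the file headers. It was not scaled between arrays, and the lowest values share a floor of 4.25 in DMSO and 3.51 in SKI-5C. The authors also deposited a table of log2 values for 41925 probes. Each column of it ranks as the processed intensity of its own array (rho 1.00, against 0.941 for the other array), with medians of 6.27 and 6.26, so it holds log2 levels and no ratio. How the authors normalized and filtered that table is not given in the sources used here. It leaves out 860 probes measured on both arrays, and it does not list the 20 named genes.

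The main value was log2 of the processed intensity minus the 75th percentile of each array's transcript probes. The 60 negative control probes and other controls were left out of that percentile. Probes had to be well above background on both arrays and free of saturation, non-uniformity and population-outlier flags, which left out 16 probes. Spots of a probe were averaged. The 75th percentile differed by 0.03 between arrays on the log2 scale. A probe well above background on 1 array only was given a lower bound against the lowest signal well above background on the other, 21.3 in DMSO and 17.6 in SKI-5C. With 1 array per group no test was run, and differences are described by size, at 2-fold. For 40 replicated probes the SD of the log2 differences taken spot by spot, at the same place on both arrays, ranged from 0.03 to 0.35, with a median of 0.10. The SD of a spot difference given for named genes is another quantity, the root of the summed squares of the spot SDs of both arrays, up to 0.45. Both cover spot noise within an array only. Slide and scan were shared by both arrays and cannot separate the groups, but position on the slide (array 1 or 2) goes with the group.

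The size count was tested on simulated data for SKI-5C against DMSO with 36575 probes, of which 200 were changed 4-fold. All of the changed probes (100%) were recovered, and 31 unchanged probes passed 2-fold from simulated scanner error alone. The simulated unchanged probes had an SD of 0.25, against 0.67 for the measured probes. The 31 therefore cannot be set against the counts on the real arrays.

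Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, cyclic loess, the value table, other filters on dim probes, outlier spots kept, the brightest probe of a gene, and thresholds of 1.5 and 3. Normexp used median spot and background intensities in place of the planned mean spot intensity, which was not used here. Removal of position medians, omission of the left columns, the value table with all its probes, and an offset of 0 were added after seeing the data. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

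The files used here pair no gene with 58945 of the probes. The 20 probes with RefSeq accessions all matched a symbol, without version, in a RefSeq gene table of assembly GRCh38.p14, whose coordinates were not used because the array design is on another build. The rule for named genes, fixed before the data were examined, took the largest coding and noncoding differences, members of 36 gene lists and a fixed set of genes that began with SPHK1 and SPHK2. It could not be applied, because 3 lists had a named member, at most 2, where 5 were needed. The genes that the files name are reported instead, except for 2 whose values are not reported here, with up to 2 probe IDs per direction from the brighter part of the probes that were 2-fold different in the main setting, with normexp and in the value table. The split into coding and noncoding transcripts, the gene list medians, the cell type markers and the fixed genes were not analysed here.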

Results

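RNA abundance was measured in SK-NEP-1 cells, a human line that the labels describe as derived from a kidney Wilms' tumour and that is also known to carry the EWSR1-FLI1 fusion of Ewing sarcoma. One culture received the vehicle DMSO and the other 2 µM SKI-5C, a compound known as an inhibitor of sphingosine kinase, the enzyme that makes sphingosine 1-phosphate. The labels give a time of 24 hours, taken here as that of the treatment, although the wording is ambiguous. Each group was represented by 1 array, a single-colour (Cy3) Agilent array of coding and long noncoding transcripts. There were no replicates, so no difference has a replicate check and no p-value is given for any gene. The errors below are spreads between copies of a probe on an array and cover neither cultures nor labelling. Of 58965 transcript probes, 38919 (66.0%) were well above background in DMSO and 39089 (66.3%) in SKI-5C. Of 600 negative control spots, 90 in DMSO and 68 in SKI-5C passed as well, so passing alone does not show that a transcript was present. Both arrays lay on the same slide and came from the same scan. No spot was saturated, and the small number of arrays limits the precision.

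The comparison asks which transcripts differed after SKI-5C. The array files name genes only for 20 replicated probes and for 4 control probes of GAPDH and PGK1, and these are mostly abundant housekeeping genes. The sphingosine kinase genes were not analysed here. None of the 20 genes differed by 2-fold or more. In SKI-5C, 6 were higher and 8 lower by more than 1 SD of a spot difference, and 6 lay within it. This SD combines the spot SDs of both arrays (root of their summed squares) and is the error given for single genes. It leaves out outlier-flagged spots and can be wider with them kept. For MTX1 it was 0.06 over 7 spots and 0.16 over all 10.

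ARHGDIA, a GDP dissociation inhibitor, was 1.23-fold higher in SKI-5C, or 0.30 ± 0.08 on the log2 scale (10 spots). It was above 0 in all 6 settings of scaling, background and position correction tried, but its size depended on the scaling. ARHGDIA was at 0.11 after quantile normalization and at 0.06 after cyclic loess, the latter within its SD of 0.08. The probes nearest to it in brightness had a median difference of 0.19, and ARHGDIA stood at percentile 66.5 among them. H3-3A, which encodes a replication-independent histone H3.3, was higher by 0.23 ± 0.11 on the log2 scale but at −0.01 after cyclic loess. MTX1, a protein of the outer mitochondrial membrane, was higher by 0.23 ± 0.06 but at −0.04 after quantile normalization and −0.02 after cyclic loess. ODC1, the rate-limiting enzyme of polyamine synthesis, was higher by 0.09 ± 0.04 and at −0.15 after cyclic loess. H3-3A, GAPDH, PGK1, the actins and the ribosomal protein genes have near-identical copies, repeats or pseudogenes elsewhere in the genome, so their values are uncertain as to the gene of origin.

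The 8 genes that were lower stayed below 0 in all 6 settings, but their size depended on the scaling. Quantile normalization brought all 8 nearer to 0, with GAPDH at −0.08 and ACTB at −0.10, the latter within its SD. Cyclic loess moved all 8 further below 0. The cytoskeletal genes ACTG1 and ACTB had log2 differences of −0.46 ± 0.06 and −0.27 ± 0.12, which puts ACTG1 1.37-fold lower. Among genes of the translation machinery, RPS18 was at −0.42 ± 0.12, RPLP1 at −0.42 ± 0.09 and RACK1, a scaffold on the small ribosomal subunit, at −0.28 ± 0.11. GAPDH, a glycolytic enzyme, was at −0.31 ± 0.06. DYNLL1, a dynein light chain, was at −0.26 ± 0.13. COX4I1, a subunit of cytochrome c oxidase, was at −0.21 ± 0.09 and close to 0 (−0.01) after quantile normalization. PFN1, EIF3D, PRMT1, PGK1, GRM4 and RPL10 lay within 1 SD of a spot difference of 0. The GRM4 and RPL10 probes were dim, with signals of 55.7 and 43.4 in DMSO, and RPL10 had the widest SD of a spot difference among the named genes, 0.45. The negative control probe Negative059 read 72.3 in DMSO, so these 2 signals may not come from the genes.

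**Figure D1:**
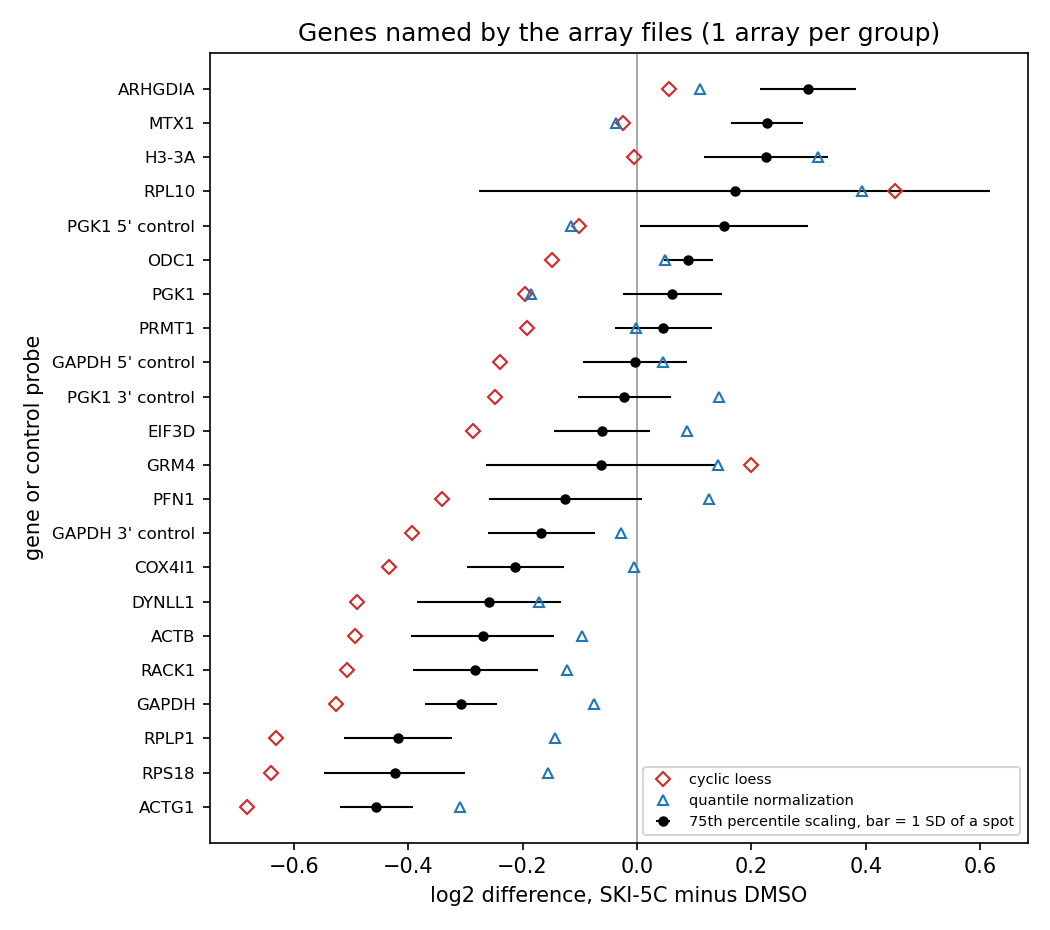
Log2 difference in signal, SKI-5C minus DMSO, for the named genes reported and the 4 control probes of GAPDH and PGK1. Black points are means over spots after scaling to the 75th percentile, with 1 SD of a spot difference, and open symbols give the same genes after cyclic loess or quantile normalization. Among the genes shown ARHGDIA is highest at 0.30 and ACTG1 lowest at −0.46, while, of those beyond 1 SD from 0, H3-3A, MTX1, ODC1 and the 5′ control of PGK1 cross 0 after cyclic loess, and MTX1 and the PGK1 control also after quantile normalization.

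GAPDH and PGK1, both glycolytic enzymes, were each measured by 3 probes. For GAPDH the probes gave −0.31, −0.17 at the 3′ control and −0.004 at the 5′ control, a mean of −0.16 ± 0.15 (SD over probes). For PGK1 they gave 0.06, −0.02 at the 3′ control and 0.15 at the 5′ control, a mean of 0.06 ± 0.09. The 5′ control of PGK1 was at −0.12 after quantile normalization and −0.10 after cyclic loess. The log2 difference at the 3′ control minus that at the 5′ control was −0.16 ± 0.04 for GAPDH and −0.17 ± 0.05 for PGK1 (SE over spots). These contrasts depend on the scaling. After quantile normalization the order turned for PGK1, with 0.14 at the 3′ control, and GAPDH was at −0.03 (3′) and 0.05 (5′). After cyclic loess the order was kept for both genes. The PGK1 controls also differed in brightness, with mean log2 signals of 17.2 (3′) and 13.7 (5′).

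Among the 36595 probes measured on both arrays, the log2 difference had a median of −0.08 and an SD of 0.67. By size alone, 2106 probes (5.75%) were at least 2-fold higher in SKI-5C and 2283 (6.24%) at least 2-fold lower, so that 48.0% of these probes were higher. This split depended on the scaling. The higher share was 56.3% after quantile normalization, 63.6% after median centring and 61.1% after cyclic loess. It was 77.8% after normexp background correction and 55.0% in the authors' deposited value table. Median centring moved the median of all probes from −0.08 to 0.02, a shift above 0.1. At least 2-fold differences in all 4 of the main setting, normexp, the value table and cyclic loess were seen for 693 probes higher and 308 lower. A further 2476 probes were well above background only in SKI-5C and 2303 only in DMSO. Against the lowest signal well above background on the other array, 238 of the former were at least 2-fold higher and 491 of the latter at least 2-fold lower. These 2 counts are not on equal terms. That lowest signal was 21.3 in DMSO and 17.6 in SKI-5C, so a fall passed from a weaker signal than a rise.

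The difference followed brightness. The median log2 difference was −0.31 in the dimmest decile of the probes and 0.29 in the brightest. The dimmest decile is shaped in part by the filter on both arrays. The lowest signal well above background was 21.3 in DMSO and 17.6 in SKI-5C, which favours falls among probes near these limits. In that decile 6 probes were at least 2-fold higher and 267 at least 2-fold lower. The named genes with the strongest signals, 14 with a mean log2 signal of 16 or more, had a median difference of −0.24, with 10 lower and 4 higher. After cyclic loess 13 of the 14 were lower, with a median of −0.46, while after quantile normalization 9 were lower and 5 higher, with a median of −0.04. Before cyclic loess, the 200 probes nearest in brightness to each of the 14 had medians from −0.05 to 0.06. Cyclic loess thus lowered these genes by more than probes of like brightness called for, so its values here may be too low. Among the 200 probes nearest to each in brightness, ACTG1 stood at percentile 5.0, RPS18 and RPLP1 at 6.0 and H3-3A at 78.5. For 10 of the 14 genes these were one and the same set, which reached down to a log2 signal of 15.94.

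**Figure D2:**
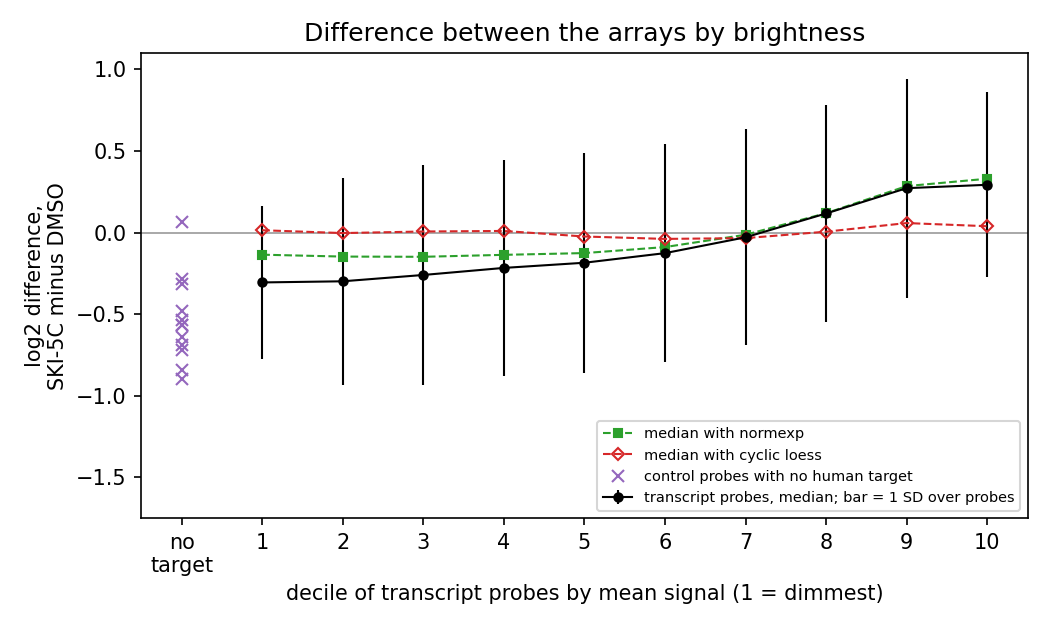
Median log2 difference, SKI-5C minus DMSO, in deciles of the measured transcript probes ordered by mean signal (bars, 1 SD over probes), with normexp and cyclic loess medians. The median goes from −0.31 in the dimmest decile to 0.29 in the brightest, and crosses mark 12 control probes taken to have no human target, of which 11 were lower in SKI-5C.

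The probes with the largest differences could not be tied to genes in the files used here. Among brighter probes that passed 2-fold in 3 settings, the most strongly higher in SKI-5C were ASHGA5P000921, with a signal of 872 in DMSO and 50783 in SKI-5C, and ASHGA5P028211, with 52.3 and 2495. The most strongly lower were ASHGA5P026868, with 68651 in DMSO and 342 in SKI-5C, and ASHGA5P056651, with 9466 and 151. Outlier-flagged spots within 2 rows and columns numbered 2 for ASHGA5P000921, 4 for ASHGA5P026868, which lay in column 1 at the edge of the array, and 1 for ASHGA5P056651. Both of the lower probes were among the 10 largest falls before filtering, all of which carried an outlier flag or lay beside another of the 10. Probes that were at least 2-fold lower were unevenly placed. Over 72 blocks of the array their share ranged from 1.74% to 19.2%, and it was 9.85% in the leftmost 55 of 164 columns against 4.57% elsewhere. The share of higher probes ranged from 2.05% to 10.4%, and was 6.69% in the same left columns against 5.33% elsewhere.

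**Figure D3:**
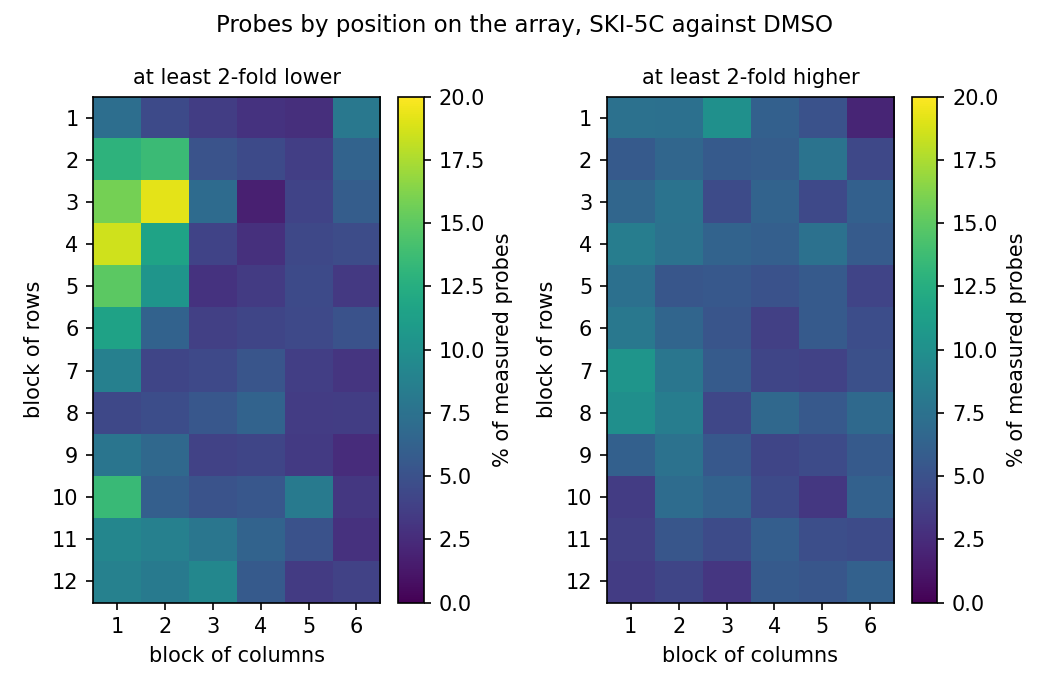
Percent of measured probes at least 2-fold lower (left) and at least 2-fold higher (right) in SKI-5C, in 72 blocks of the array laid out by rows and columns. The share of lower probes reaches 19.2% and that of higher probes 10.4%, both on the left side of the array, and the lowest share of higher probes is 2.05%.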

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

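The tests of damaged spots and of nonspecific binding were chosen after their results had been seen, and the subtraction of block medians and the offset on the left were added after the correlation over blocks was known. A mouse control probe outside the main measurement stood above background on all its spots: the 5′ PGK1 probe of mouse had a log2 difference of 0.12 ± 0.11 (SD of spots), with signals of 5363 in DMSO and 5933 in SKI-5C. The other mouse and rat probes above background on all spots were at −0.51 (mouse PGK1 3′), −0.37 and −0.21 (mouse GAPDH 5′ and 3′), −0.52 and −0.04 (rat GAPDH 3′ and 5′) and 0.09 (rat PGK1 5′).

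Dim probes tended to be lower in SKI-5C and bright probes higher, with medians of −0.26 in the dimmer and 0.13 in the brighter part of the transcript probes. The filter favours falls near its limits, 21.3 in DMSO and 17.6 in SKI-5C, and its share in the dim part was not tested. The control probes below had to pass the same limits. Weaker nonspecific binding on the SKI-5C array is a candidate explanation for the dim part. Control probes taken to have no human target, 12 in all, had a median log2 difference of −0.57 and 11 were lower, from −0.90 to 0.06. Without the 6 whose design is least certain the median was −0.51, and after cyclic loess the median of the 12 was −0.25. The higher values of bright probes are not accounted for by this test, and an effect of SKI-5C on weakly expressed transcripts stays open and untested.

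Probes at least 2-fold lower were concentrated on the left of the array, more so in the dimmer part of the probes (15.5% against 6.07% elsewhere) than in the brighter (4.33% against 3.06%). Residual background on the DMSO array stays open, because its values go both ways. The negative control signal of DMSO minus SKI-5C followed the share of lower probes over 72 blocks (rho 0.34, two-sided permutation p = 0.00351). The permutation takes blocks as exchangeable, although adjoining blocks had similar shares, so this p is likely too small. Within the left blocks rho was 0.16, and within the others 0.43. The same signal difference was 0.0018 ± 0.60 units on the left (bootstrap SE, 322 spots) and −7.09 in the block with the highest share. With normexp the shares were 0.846% on the left and 0.868% elsewhere at an offset of 50, which shrinks dim differences everywhere, and 4.52% and 2.11% at an offset of 0; with the negative control median of each block subtracted they were 8.41% and 4.87%. Grouping by place of transcripts with consecutive IDs is argued against, because their probes lay 0.987 times as far apart as random pairs. Grouping in an order other than that of the IDs was not tested. The design gives no biological explanation for place on the array and none was tested.

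The largest falls before filtering, up to −11.87 on the log2 scale, could come from damaged or dirty spots. All 10 of the 10 largest carried an outlier flag or lay beside another of them, 8 with a flag, against 3 of the 10 largest rises. The share of flagged probes overall was 0.0437%. Of the 10 falls, 4 lay in column 1. A fall of the transcripts themselves was not tested.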

How the results depend on the processing

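No paired analysis was possible because each group has 1 array and no test was run. Settings added after seeing the data were removal of position medians, omission of the left columns, the value table with all probes and an offset of 0. The main counts at 2-fold were 2106 higher and 2283 lower. Counts moved by over 1.5 times with normexp (1103 higher, 315 lower), no filter on dim probes (4097 and 6478), thresholds of 1.5-fold (5676 and 7439) and 3-fold (459 and 211), and omission of the left columns (1331 and 1142, with fewer probes). Only the lower count did so with the value table (1510), cyclic loess (1484), the brighter part of the probes (634, fewer probes) and an offset of 0 (1050). Only the higher count did so with all probes of the value table (3228, more probes). Where filter, threshold or number of probes does not set the count, the cause was not tested. Of the 24 named probes, all moved by less than 1 SD of a spot difference with normexp, outlier spots kept and position medians removed; 14 moved further with median centring, 18 with quantile normalization and 23 with cyclic loess. Among probes beyond 1 SD from 0 the sign turned for ODC1 (−0.15), H3-3A (−0.0054), MTX1 (−0.024) and the PGK1 5′ control (−0.10) after cyclic loess, and for MTX1 (−0.036) and the PGK1 5′ control (−0.12) after quantile normalization; the cause was not tested. Among probes within 1 SD it turned for 3 with cyclic loess, 7 with quantile normalization, 4 with median centring and 1 with normexp. Class and list results, random lists without matching, scaling over coding probes and the value table for named genes were not run. Weak signal limits the counts: the median transcript signal was 47.9 in DMSO and 41.7 in SKI-5C.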

Other observations

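The test of compression at high signal was chosen after its result had been seen. Probes with consecutive IDs moved together. After medians of position and brightness were taken out, their log2 differences correlated across 23843 pairs of probes with r 0.101, above the highest of 1000 random pairings (0.0179); probes are not independent replicates. The correlation was 0.04 for probes 10 IDs apart and 0.03 for those 100 apart, and 0.158 for pairs of bright probes against 0.08 for dim ones. Both members of 474 pairs passed 2-fold, of which 71.3% went the same way against 50.1% expected. Both were higher in 213 pairs, against 79.1 expected, and both lower in 125, against 92.9. The expected numbers come from the main 2-fold shares of all probes and take the 2 members of a pair as independent. They allow for neither brightness nor position. Consecutive IDs lay a median of 136 spots apart, so shared position is argued against. A hypothesis is that these differences reflect RNA of related transcripts, which may have neighbouring IDs; it concerns RNA on these arrays and not an effect of SKI-5C, and the files used here do not say how IDs were assigned.

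Runs of consecutive IDs that all passed 4-fold numbered 12 higher and 1 lower. The longest held 4 probes, with log2 differences of 3.59 to 3.79 in SKI-5C, at least 3.34 with normexp and at least 3.35 after cyclic loess. The smallest distance between probes of this run was 4.24 spots, and it has no result from the authors' value table. No number of runs expected at random is given.

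The brightest named genes were mostly lower in SKI-5C, with a median of −0.24 over 14 genes, which was −0.04 after quantile normalization, with 5 of the 14 higher. Compression of strong signals was considered, and the comparison with the 200 probes nearest in brightness could not decide it. The 14 genes lay at a median of −0.19 from those probes, with an SD of 0.25 over genes. For 10 of them the set was the same and reached down to a log2 signal of 15.94, so it does not match the very brightest genes. Genes of like brightness differed, with DYNLL1 at −0.26 ± 0.13 and H3-3A at 0.23 ± 0.11, both at a mean log2 signal of 16.9. Compression set by brightness alone would not give this, which argues against it as the source of the differences among these genes. Its share in their common fall stays open. A lower level of these transcripts after SKI-5C was not tested, since each group has 1 array.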
